A study of Drosophila melanogaster with 3 samples.

How the data were processed

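Early replication origins were mapped in S2-DRSC, a male Drosophila melanogaster cell line derived from embryos. Per the labels' protocols, cells grown at 25 °C were held for 3 h in 1 mM hydroxyurea (HU), which blocks ribonucleotide reductase and so starves replication forks of nucleotides. They then received 50 µg/ml bromodeoxyuridine (BrdU), a thymidine analogue that marks newly made DNA, and were harvested 20 h later. BrdU-containing DNA was immunoprecipitated, labelled with cyanine dyes and hybridised to 2-colour Agilent tiling arrays. The labels name 3 extractions, each on 1 array, as replicates 1 to 3 of a single group. Nothing in the labels says that the extractions came from separate cultures, so the p-values may measure technical spread only.

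Scanner files gave spot intensity values that were made with Agilent Feature Extraction 9.5.1.1, per the file headers. Its processed intensities were already background-subtracted, spatially and multiplicatively detrended and linearly dye-normalized, per the file headers. The mean and local background intensities in the same deposited files were unprocessed. The authors also deposited, for each array, a probe score named MA2C in the file name and a normalized log2 ratio in the file header. Its mean was 0 and its SD 1 on every array, so these deposited values were treated as a score and not as a plain log2 ratio. Medians of that score were -0.116, -0.144 and -0.158 on arrays 1, 2 and 3. A single list of early origin peaks for the whole series carried the authors' own peak score, whose scale is not given in the sources used here. The list names pMA2C as its source, and whether the arrays were pooled for it is not given in the sources used here. That score was used only to describe, rank and filter the peaks. Probe positions followed FlyBase release 5.1 and peak positions FlyBase release 5.3, per the file headers. Both belong to genome release 5, and coordinates were used as the files give them.

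Each array held 241469 probes of 45 to 60 bases with a median spacing of 470 bp, and 1804 control spots that were left out. Spots that Feature Extraction had marked as outliers were also left out, 295, 354 and 19 on arrays 1, 2 and 3. For each probe the log2 ratio of the processed Cy5 over the processed Cy3 signal was centred on the array median, with no loess or quantile step. Every array carried Cy5 in channel 1 and Cy3 in channel 2, per the labels, which do not say which channel held the BrdU precipitate or what the other DNA was. The as-recorded ratio of array 3 ran opposite to arrays 1 and 2, while the authors' MA2C scores ran the same way on all 3. The score correlated with the Cy5 over Cy3 ratio at r = 0.813, 0.823 and -0.980 on arrays 1, 2 and 3, so the authors had turned array 3. Array 3 was therefore turned here too, before averaging. A positive value is likely enrichment in the BrdU precipitate, on the basis of its sign inside the authors' early origin peaks; that direction is not settled by the labels, and with every sign turned, above and below change places throughout. Arrays 1 and 2 were scanned on the same day and array 3 on another, so scan day and dye orientation cannot be told apart, and values over arrays 1 and 2 alone are the within-batch values.

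Windows of 10 kb with at least 10 probes were averaged on each array and tested against 0 with an intercept-only model in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation. Adjusted p-values are Benjamini-Hochberg values over all windows at a threshold of 0.05. Windows past it are called above or below the array median. Neighbouring windows share labelled DNA fragments and are not independent. Inside and outside peaks were compared by probe midpoints, with an exact sign-flip permutation test over the 3 arrays (smallest two-sided p 0.25) and with 1000 rotations of the peaks within each arm. The share of probes in peaks on the X and on the 4 major autosome arms was compared with 1000 rotations of the peaks over the joined arms. Both rotation p-values are two-sided, and for the median in place of the mean 200 rotations were used. The named regions, fixed before the data were examined along with the tests, were the 10 highest and 10 lowest called windows with 1 sign on all 3 arrays and at least 50 kb apart, and the 10 peaks of at least 3 probes with the highest mean ratio. Further calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

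The window test was tested on simulated data of 11533 windows. It recovered 10% of 50 windows shifted by 0.25 on the log2 scale, 81% of 100 shifted by 0.5 and 92% of 50 shifted by 1. Of 11333 unshifted windows, 1 was called. Most simulated windows were unshifted and all were independent, whereas 8362 of the measured windows were called and neighbours are not independent. The adjusted cutoff was therefore stricter in the simulation, and these shares do not carry over to the measured windows. For the peak comparison, 3.5% of 200 random placements gave a rotation p under 0.05.

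Alternatives were normexp background correction with an offset of 50, loess within arrays, the deposited MA2C scores, only probes well above background, a correction for probe GC content, leaving out each replicate, windows of 5 and 25 kb, single probes, window medians, a zero point at the array mode, a threshold of 0.01, a minimum size of 0.5 on the log2 scale, and only peaks that scored at or above the median. Leaving array 3 unturned and a dye effect as a model term were chosen after seeing the data. Comparisons by gene, by gene list and by distance from gene starts had been planned and were not run, because the gene table used here follows genome release 6 and coordinates were not converted between releases. No gene is therefore named. The number of arrays limits the precision.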

Results

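The 3 arrays measured, along the Drosophila genome, how much DNA carried BrdU in S2-DRSC cells held in HU, relative to the DNA in the other channel. Under HU, origins that fire early take up BrdU around their start sites, while forks travel only a short way and late origins stay mostly silent. Between 99.3% and 99.9% of the probes were well above background in each channel of each array. The median spot intensity was 171, 204 and 454 in Cy3 and 590, 638 and 559 in Cy5 on arrays 1, 2 and 3. All log2 ratios are relative to the median of the array, with array 3 turned, and positive values likely stand for BrdU enrichment.

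The first question was whether the 3 extractions gave the same profile. Once array 3 was turned, the 11533 windows of 10 kb correlated across the genome with Pearson r of 0.969 between arrays 1 and 2, 0.965 between 1 and 3 and 0.972 between 2 and 3. Spearman rho was 0.953, 0.950 and 0.951 for the same pairs. Windows are not independent replicates, so no p-value is attached. As recorded, the Cy5 over Cy3 ratio of array 3 correlated with arrays 1 and 2 at -0.965 and -0.972. Over single probes, r fell to 0.838, 0.796 and 0.784 with array 3 turned. The arrays also differed in scale, with window SDs of 0.49, 0.44 and 0.35, and array 3 was the most compressed. In all, 10008 windows (86.8%) had 1 sign on all 3 arrays, where independent signs would give 25%. Turning array 3 fixed the direction of its agreement, so this share is not evidence separate from the correlations. Because the labels do not settle the direction, each result also has a mirror image: with every sign turned, 4271 windows would be above the median and 4091 below, probes inside peaks would average -0.95, X minus autosomes would be -0.06, and the highest and lowest regions would change places.

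Of the 11533 windows, 4091 (35.5%) lay above the array median, 4271 (37.0%) below it and 3171 on neither side by limma's adjusted p. Windows above the median reached further from it than those below, with a median log2 ratio of 0.38 against -0.27. A mean ratio over 1 was found in 456 windows, while 0 windows had one below -1. The highest window stood at 2.53 and the lowest at -0.90. Contiguous windows above the median formed 1251 runs, the longest of 380 kb on 2L at 17580001 to 17960000, with a mean log2 ratio of 0.40 ± 0.08 (SD, n = 3). The next longest covered 370 kb on 3L at 18150001 to 18520000 and averaged 0.47 ± 0.08 (SD, n = 3). The 1294 runs below the median were shorter at their longest, 230 kb on 2R at 20590001 to 20820000, with a mean of -0.39 ± 0.08 (SD, n = 3).

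**Figure D1:**
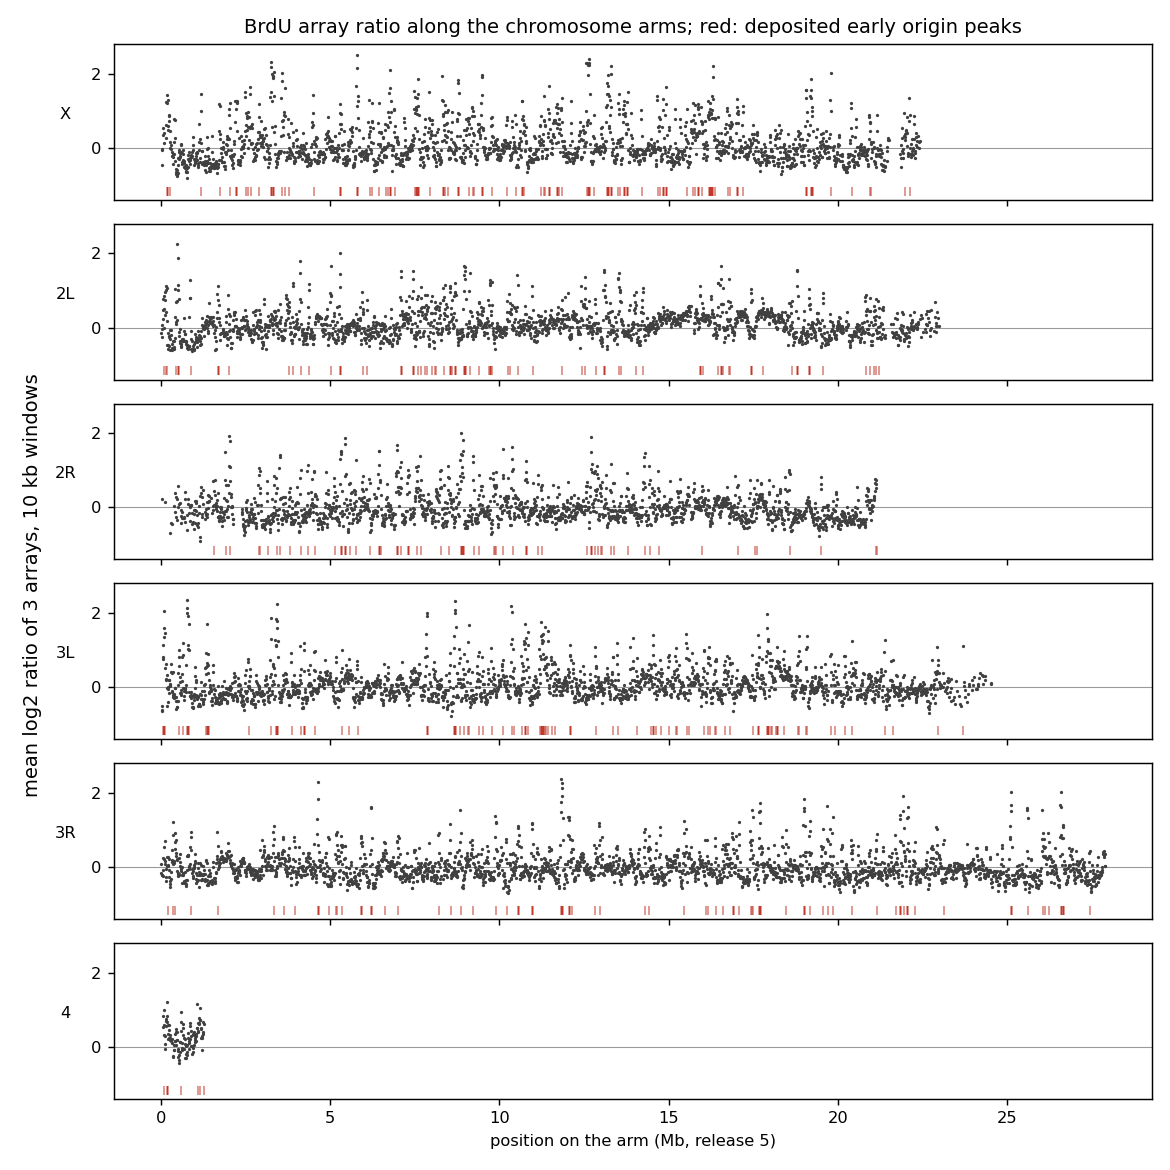
Mean log2 ratio of the 3 arrays in 10 kb windows (points) against position in Mb on the X, the 4 major autosome arms and chromosome 4, with the deposited early origin peaks as red bars under the points. Tall maxima reach above 2 on the X and the 4 major autosome arms and sit over deposited peaks, while 0 windows fall below -1. The peaks were called by the authors from these same arrays.

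All 10 of the named highest windows lay wholly inside deposited peaks. The authors called those peaks from these same arrays, so this overlap is not independent evidence. The highest, 5290001 to 5300000 in unplaced sequence (U), reached 2.53 ± 0.18 (SD, n = 3), and this is a lower bound, since 16 of the 33 probes of the peak around it were saturated in the brighter channel on all 3 arrays. After the GC correction this window stood at 2.29 or more, and X 5780001 to 5790000 at 2.49. What DNA this unplaced stretch is, chromosomal or mitochondrial, was not determined here. The highest window on a chromosome arm was X 5780001 to 5790000, at 2.49 ± 0.21 (SD, n = 3), which is a 5.62-fold ratio. It was followed by X 12630001 to 12640000 at 2.40 ± 0.31 (SD, n = 3) and by 3R 11810001 to 11820000 at 2.36 ± 0.33 (SD, n = 3). On 3L, the window 770001 to 780000 reached 2.36 ± 0.27 and the window 8680001 to 8690000 reached 2.32 ± 0.30 (SD, n = 3). The remaining 4 were X 3250001 to 3260000, X 12570001 to 12580000, 3R 4630001 to 4640000 and 2L 480001 to 490000, with means from 2.30 down to 2.25.

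The lowest windows lay outside peaks, which again is not independent evidence. The window 8580001 to 8590000 on 3L fell to -0.78 ± 0.20 (SD, n = 3), 100 kb from the 3L window that reached 2.32. Similar valleys were X 760001 to 770000 at -0.82 ± 0.37, X 480001 to 490000 at -0.75 ± 0.29, 2R 19430001 to 19440000 at -0.76 ± 0.20 and 2R 2450001 to 2460000 at -0.73 ± 0.18 (SD, n = 3). 2R 9760001 to 9770000 stood at -0.73 ± 0.25 and 3L 22680001 to 22690000 at -0.70 ± 0.19 (SD, n = 3). The other 3 rest on dim probes. In U 6350001 to 6360000 (-0.90 ± 0.67), 2R 1150001 to 1160000 (-0.89 ± 0.70) and YHet 30001 to 40000 (-0.71 ± 0.57; SD, n = 3), only 4 of 11, 7 of 13 and 5 of 16 probes were well above background on all 3 arrays. On array 3 these 3 windows stood at -0.13, -0.16 and -0.10.

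**Figure D2:**
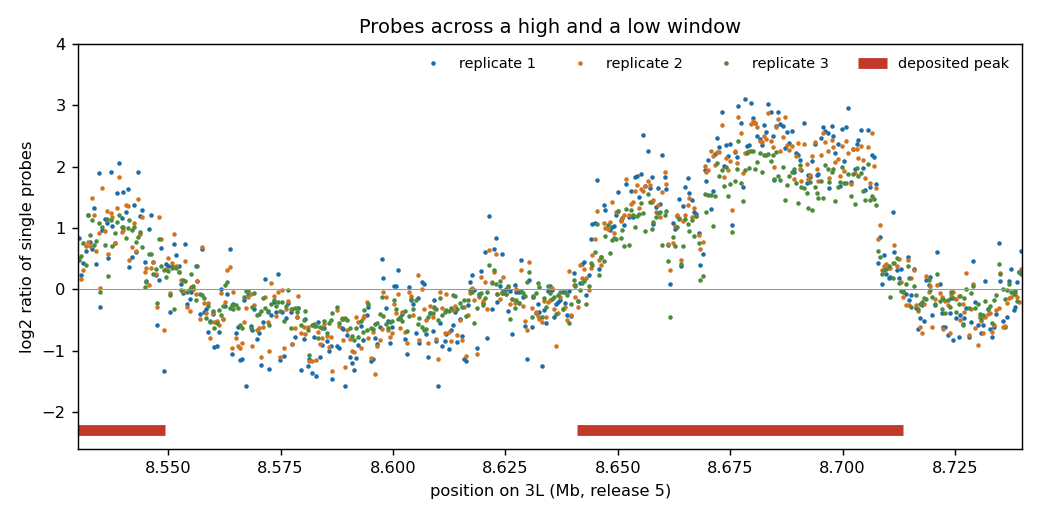
Log2 ratio of single probes on each of the 3 arrays (colours) against position in Mb on 3L from 8530001 to 8740000, with the 2 deposited peaks as red bars. Window means fall to -0.96, -0.81 and -0.56 on arrays 1, 2 and 3 at 8580001 to 8590000 and climb to 2.53, 2.45 and 1.98 at 8680001 to 8690000.

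Normexp background correction with its offset of 50 left 2169 windows above and 1178 below, and a zero point at the array mode gave 5360 above and 2617 below, so that 67.2% of the called windows were above it instead of 48.9%. Over arrays 1 and 2 alone, which shared a scan day, 4104 windows were above and 4355 below; with array 3 left unturned limma called 0 windows, and 0 had an unadjusted p under 0.05.

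The second question was how large the enrichment was in the regions that the authors listed as early origins. The list held 457 peaks that covered 13.5 Mb, with widths from 10.0 to 162 kb and a median of 23.2 kb. Every one of the 457 had a mean log2 ratio above 0 on all 3 arrays. Probes inside peaks averaged 0.95 ± 0.12 and probes outside -0.04 ± 0.02 (SD, n = 3). The level inside peaks was 1.04, 0.99 and 0.81 on arrays 1, 2 and 3. The difference between inside and outside was 0.99 ± 0.14 (SD, n = 3), a 1.99-fold ratio. It exceeded all 1000 rotations of the peaks along the arms, the largest of which gave 0.29 (rotation permutation p = 0.001, the smallest these can give). The exact sign-flip permutation test over the 3 arrays gave p = 0.25, also the smallest it can give. The peaks were called by the authors from these same arrays, so the difference is a size and not independent evidence. Arrays 1 and 2 alone gave 1.07 ± 0.05 (SD, n = 2), and leaving array 3 unturned gave 0.44, with array 3 itself at -0.83.

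Single peaks averaged from 0.43 to 2.55, with a median of 0.80. The average profile of the peaks was highest at their midpoints and fell off smoothly on either side. It pools peaks of unlike width and need not be the shape of a single peak. Averaged over peaks, the ratio was 1.05 ± 0.13 within 5 kb to the right of the midpoint, 0.55 ± 0.08 at 10 to 15 kb, 0.29 ± 0.03 at 20 to 25 kb and 0.09 ± 0.00308 at 45 to 50 kb (SD, n = 3). At 95 to 100 kb it was 0.09 ± 0.01 (SD, n = 3).

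**Figure D3:**
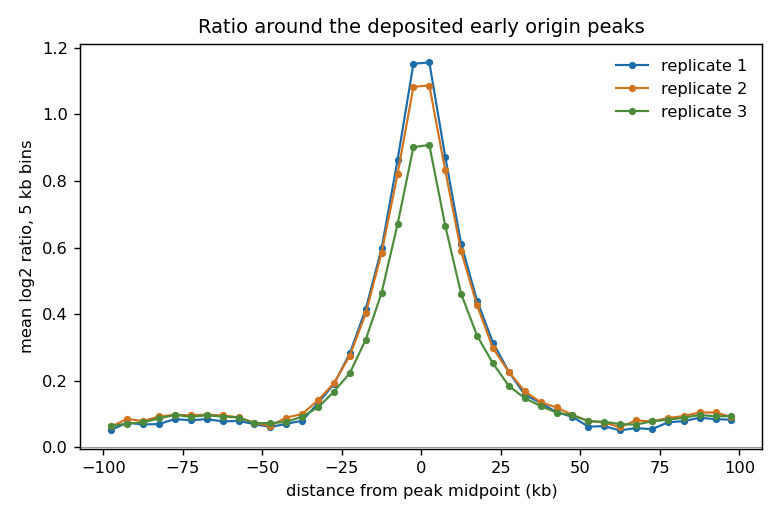
Mean log2 ratio in 5 kb bins against the distance in kb from the midpoints of the deposited peaks, 1 line for each of the 3 arrays. Replicates 1 and 2 peak at 1.16 and 1.09 and replicate 3 at 0.91, and the 3 lines run together beyond 45 kb.

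The peak with the highest mean ratio, U 5282551 to 5308300, reached at least 2.55 ± 0.19 (SD, n = 3), with saturated probes as above, and had the highest of the authors' scores, 421.06. On the X, the peak 12594291 to 12678831 averaged 1.67 ± 0.24, and its neighbour 12547411 to 12589816 averaged 1.48 ± 0.24 (SD, n = 3). A second pair on the X lay at 3226781 to 3274425, with 1.62 ± 0.22, and at 3278171 to 3354753, with 1.66 ± 0.19 (SD, n = 3). The peak X 5763831 to 5837755 averaged 1.56 ± 0.18, and 3R 11791751 to 11880116 averaged 1.62 ± 0.26 (SD, n = 3). On 3L, the peaks 8640831 to 8713326, 751401 to 842295 and 10335211 to 10384770 averaged 1.55 ± 0.23, 1.53 ± 0.23 and 1.46 ± 0.20 (SD, n = 3). Of all peaks, 55 were at least 50 kb wide and 5 at least 100 kb. The widest was X 16160411 to 16322191, 162 kb long with a mean of 1.16 ± 0.15 (SD, n = 3), and the second widest was 2R 8827831 to 8940412, 113 kb long with 1.25 ± 0.17 (SD, n = 3). Across peaks, which are not independent replicates, the authors' score had a Spearman rho of 0.88 with width and 0.81 with the mean ratio.

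Peaks and called windows did not cover the same ground. Of 1323 windows with at least 50% of their length in a peak, 1319 were above the array median and 0 below it. The peaks came from these same arrays, so that overlap is not independent evidence. But of the 4091 windows above the median, 2436 (59.5%) touched no peak at all. Those windows had a median log2 ratio of 0.27, against 0.84 for the called windows inside peaks. Of all 9777 windows that touched no peak, 24.9% were above the median. The window call set no minimum size, whereas single peaks averaged at least 0.43, so the 2 thresholds are unlike. The highest windows outside peaks were X 22020001 to 22030000, X 16150001 to 16160000 and X 16440001 to 16450000, each at 0.83 with SDs of 0.13, 0.15 and 0.13 (n = 3). They were picked after their values were seen. The first of them rested on 10 probes, the fewest a window could have. The second lay directly beside the widest peak, X 16160411 to 16322191, so it may be the flank of that peak.

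The third question was how the early origins were spread over the chromosome arms. The X held 104 peaks or 4.64 per Mb, while the 4 major autosome arms held 342 or 3.54 per Mb. There were 85 peaks on 2L, 75 on 2R, 98 on 3L and 84 on 3R, which had the fewest per Mb at 3.01. Chromosome 4, which is small and largely heterochromatic, held only 7 peaks. At 5.75 per Mb these were denser than on the X, and 16.6% of its probes lay in peaks. The heterochromatic and unplaced sequences held the other 4 peaks. Of the X probes 16.1% lay in peaks, against 10.4% on the autosome arms, a difference of 5.66 percentage points (two-sided rotation permutation p = 0.046, by absolute size). The central 95% of the rotations ran from -4.07 to 5.85, which still holds that difference, so the excess is borderline. The median of the peak means was 0.92 on the X and 0.76 on the autosome arms, and this difference was not tested. Among the peaks that scored at or above the median of 55.7, the excess on the X was 6.16 percentage points and no longer passed the threshold (rotation permutation p = 0.054).

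The last question was whether whole arms differed in their mean ratio. 2L averaged 0.11 ± 0.03 and 3L 0.10 ± 0.01, while 2R averaged 0.00345 ± 0.00672 and 3R 0.01 ± 0.00368 (SD, n = 3). Chromosome 4 stood higher, at 0.28 ± 0.08 (SD, n = 3), with 76 of its 116 windows above the array median and 14 below. Its windows also had a lower mean GC content, 39.2%, than the X and the major autosome arms, at 41.0% to 41.5%. The mean of chromosome 4 after the GC correction was not computed. The X averaged 0.12 ± 0.07 (SD, n = 3). Its difference from the 4 autosome arms was -0.02, 0.13 and 0.08 on arrays 1, 2 and 3, with a mean of 0.06 ± 0.07 (SD, n = 3), which was within the spread between arrays (exact sign-flip permutation p = 0.5, smallest possible 0.25). Arrays 1 and 2 alone gave 0.05 ± 0.10 (SD, n = 2). The sign turned under normexp correction (-0.12), for the deposited MA2C scores (-0.01 in score units), for the median of windows (-0.01) and for windows that touched no peak (-0.03), so no direction is given for the X.

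**Figure D4:**
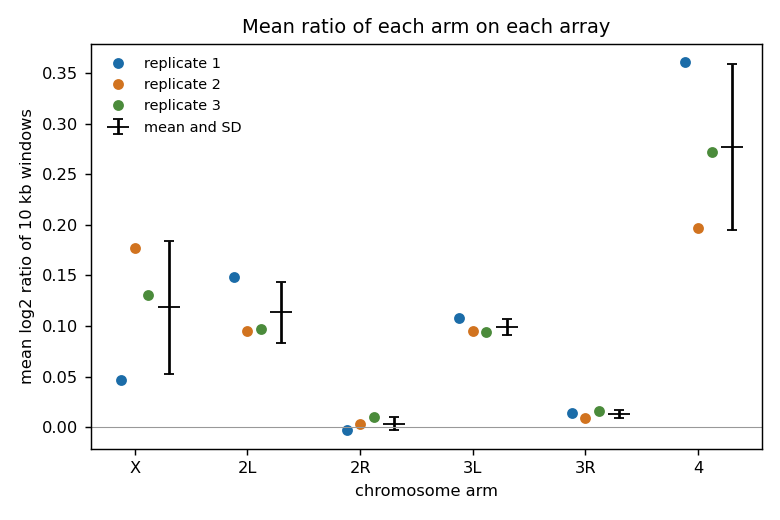
Mean log2 ratio of the 10 kb windows of each chromosome arm on each of the 3 arrays (coloured points), with the mean and SD over arrays in black. The X spreads from 0.05 to 0.18 between arrays, 2R and 3R lie near 0, and chromosome 4 lies between 0.20 and 0.36.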

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

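The tests in this part were chosen after the results they bear on were seen, and with a single group in the design no biological difference between groups was tested. The negative control spots, which enter no comparison, gave a signal. In the family of 564 control spots that share the name prefix NC2, 32.4% ± 5.33 (SD, n = 3 arrays) were well above background on average over both channels, against 7.34% ± 4.57 of the other 711 negative control spots, and the first family was higher in all 6 channels. The NC2 spots held only 77 sequences, so they are not independent. The other family stood at 17.2% and 16.0% in Cy3 of arrays 1 and 2, and at 2.11% to 3.94% in the remaining channels.

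Array 3 ran against arrays 1 and 2. If the probes themselves set the ratio through the dyes, the as-recorded profiles should correlate above 0, and the highest correlation of array 3 with the others was -0.965. That value is the reversal itself and was known beforehand. A fitted dye term had an SD over windows of 0.07, against 0.41 for the main effect, but only array 3 has the other orientation. An unrelated set of early regions on array 3 is argued against by regions picked without array 3. Of the 4104 windows called above the median on arrays 1 and 2 alone, 99.1% lay above 0 on array 3 once it was turned. Turning fixed the direction of that share, so it cannot tell exchanged channels from a sample with the reverse profile. An exchange of the 2 channels, such as a planned dye swap, stays open as a candidate explanation. The authors' scores treat array 3 as turned, but the labels record no swap. The 0.965 after turning only restates the reversal. Of the 4 ways to assign channels to the 3 arrays, 1 gave as many called windows as the assignment used, namely that one itself, with 8362 windows, and the highest of the others gave 0; 4 assignments are too few for a share under 0.05.

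The X stood lower on array 1 than on arrays 2 and 3, with a gap of -0.12 on the log2 scale relative to the autosome arms. Probe GC content is argued against, because the gap was -0.12 after the GC correction too. Dye orientation is argued against, because arrays 1 and 2 share it and differed by -0.15 (array 1 minus array 2). Background in dim probes stays open: over 10 classes of brightness the gap ran from -0.17 in a dim class to -0.0632 in the brightest, and normexp correction widened it to -0.32. With only probes well above background, X minus autosomes hardly changed, at -0.02, 0.12 and 0.08 on arrays 1, 2 and 3. That filter kept 98.5% of the X probes, so it could show little. A difference in X dose between the channels of the extractions also stays open as a hypothesis: the gap was below 0 in 12 of the 12 bins of 2 Mb on the X, and in 17 of 50 on the autosome arms. On 2L, though, the gap was above 0 in every bin but the first (-0.03) and reached 0.12 at 16 to 18 Mb. A shift of 1 sign along most of an arm was therefore not particular to the X.

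The highest ratio of the whole array lay in unplaced sequence, where 32 probes from 5288531 to 5303301 of U averaged at least 2.66 ± 0.22 (SD, n = 3), a lower bound because most of them were saturated on arrays 1 and 2. GC content, at 32.4% the lowest of all windows there, is argued against as the whole source, because 2.43 was left after the GC correction. The rank as highest window was not kept, however. After that correction the U window stood at 2.29 or more, and X 5780001 to 5790000 at 2.49. The U peak stayed above the next named peak, X 12594291 to 12678831, at 2.33 against 1.65. In the enriched channel 28, 26 and 16 of the 33 probes of the peak were saturated on arrays 1, 2 and 3, and 0 in the other channel. Whether the region is an early origin like the other peaks stays open: the ratio dropped by at least 3.52 between neighbouring probes at its left edge, but unplaced sequence joins separate scaffolds, and saturation hides the shape of the top. DNA from outside the chromosomes, such as mitochondrial DNA, is a possible source of this stretch of 14.8 kb that was not tested, since its probes were not matched to a genome.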

How the results depend on the processing

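Leaving array 3 unturned and the dye term were chosen after seeing the data. The excess inside peaks kept its direction and its rotation call in every alternative run, from 0.44 with array 3 unturned to 1.07 among log2 ratios, and 1.94 in score units for the deposited MA2C values. Without single replicates it ranged from 0.93 to 1.07, the windows above the median from 3446 to 4104 and those below from 3224 to 4355. X minus autosomes ranged from 0.03 to 0.10 without single replicates. It reversed under normexp (-0.12), with the deposited MA2C scores (-0.0108), with the median of windows (-0.00928) and in windows that touched no peak (-0.0324); the cause was not tested. The mean correlation between arrays was 0.806 over single probes and 0.844 over single probes of the MA2C scores, against 0.969 over windows. Counts above and below moved by over 1.5 times with normexp (2169 and 1178, of which 3232 calls were shared; the cause was not tested), with 5 kb windows (7773 and 8060 of 23017) and 25 kb windows (1782 and 1749 of 4665), both by the number of windows tested, with single probes (55232 and 44074 of 240802, lower shares of 22.9% and 18.3%; the cause was not tested), with a minimum size of 0.5 (992 and 7, by its construction), and with array 3 unturned (0 and 0). A zero point at the array mode left 2617 below. The excess of peaks on the X gave 6.16 percentage points with fewer peaks, those that scored at or above the median, and missed the threshold (rotation permutation p = 0.054). In the alternatives followed for single windows, the 10 highest and 10 lowest named windows kept their call in 217 cases. They lost it in 20, each with array 3 unturned, and none reversed. The threshold of 0.01, the minimum size of 0.5, other window sizes and single probes were not followed this way. With the minimum size only 7 windows were called below, so some of the 10 lowest lost their call there. The means of the named peaks moved by over 1 SD in 29 of 100 cases, 10 of them with the MA2C scores, which have another unit, 10 with array 3 unturned and 7 with normexp, and none reversed. With only well-lit probes, 3 of the lowest windows had too few probes to be tested. The gene, gene list and gene start comparisons were not run in any setting. The 2 channels were compared within each array, and no pairing between groups was possible because there is only 1 group. Signal over background limits chiefly YHet, where 40.5% of probes were well above background on all arrays.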

Other observations

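The tests in this part were chosen after the results they bear on were seen. Long stretches of the arms held no early origin peak, and they differed in level. The longest, 1816 kb on the X from 17204345 to 19020290, averaged -0.11 ± 0.09 (SD, n = 3), with 36 of 178 windows above the array median and 91 below. On 2R, 19511616 to 21091930 averaged -0.20 ± 0.03, with 20 of 153 windows above and 107 below, and on 3R 23131615 to 24841090 averaged -0.09 ± 0.01 (SD, n = 3). On 2L, by contrast, the peak-free stretch from 14251726 to 15908320 averaged 0.20 ± 0.06 (SD, n = 3), with 108 of 154 windows above and 8 below.

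No arm end was shown to differ from the rest of its arm. The last 1 Mb next to the telomere averaged -0.13 ± 0.03 on 3R, -0.13 ± 0.02 on 2R, 0.22 ± 0.03 on 3L, -0.02 ± 0.05 on 2L and -0.09 ± 0.16 on the X (SD, n = 3). Among the 10 arm ends, the lowest rotation permutation p was 0.05 (3R telomere), which was 0.5 after Benjamini-Hochberg adjustment. Windows with lower GC content had higher ratios, with a slope of -0.57 ± 0.12 per 10 percentage points of GC between windows and -0.15 ± 0.06 between probes of the same window (SD, n = 3). On YHet, all 4 windows were below the array median, at -0.62 ± 0.50 (SD, n = 3), with -1.09, -0.67 and -0.09 on arrays 1, 2 and 3.

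Early origin peaks may cluster more than chance placement gives, as a hypothesis. Between neighbouring peaks on the 5 major arms there were 441 gaps with a median of 124 kb, and 58 of them were under 20 kb. In 1000 random placements of the same peaks on the same arms the count averaged 37.1 and reached 55 at most (one-sided permutation p = 0.001, the smallest these can give). The placements also used stretches without probes, and how close 2 peaks could lie before the authors joined them is not given in the sources used here.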
